A study of Mus musculus with 12 samples.

How the data were processed

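Bulk RNA from bone marrow cells of wild-type mice was measured in 12 samples, 4 per group, taken from the labels: control, a CTX model of myelosuppression, and a group given self-assembled nanoparticles from Cornus officinalis (cornus). The design text calls the samples biological replicates. Per the submitters' processing notes, RNA was extracted with Trizol, selected with poly-T beads and amplified by PCR, and reads were trimmed with fastp 0.22.0, aligned with HISAT2 2.1.0 and counted per gene with HTSeq 0.9.1. The genome build, the annotation and the strand setting are not named.

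The deposited table gives a read count per gene and sample as whole numbers, and the tests used these counts. The deposited table also gives FPKM, which equalled count divided by the deposited gene length and 1 factor per library (largest relative departure 0), and FPKM served only as an alternative. It holds 21958 genes, of which 51 have no symbol and 21 symbols belong to more than 1 gene. Of the gene identifiers, 21850 are in GENCODE M21 and 21722 of these are protein coding (99.4%). Only 514 genes have the same start and end in GRCm38, so the coordinates are not of that build and are given as deposited. Genes withheld for evaluation are not reported here, including where the rule for named genes picks them. Library totals lay between 13902122 and 19139771 counts.

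Genes were tested in R 4.3.3 with edgeR 4.0.16 (TMM factors, filterByExpr with its defaults, quasi-likelihood F test), with all 12 samples in 1 fit and group as the only term. The threshold was a Benjamini-Hochberg adjusted p under 0.05, and 12549 genes were tested in each of 3 comparisons: model against control, cornus against model, and cornus against control. Standard errors of log2 changes are the absolute log2 change over the square root of the F value, and log2 CPM used a prior count of 2. Where a group had 3 or fewer counts for a named gene, the ratio of summed counts is given with a 95% exact binomial interval, or a bound at 3 counts if the group had none. Genes were said to have no overlap when every value of 1 group lay beyond every value of the other. Chance gives this in 2.86% of genes on average over splits, if all samples are separate. Genes vary together, so a single chance split can give a larger share.

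Sets of genes were tested with limma 3.58.1 (camera with a preset correlation of 0.01 on voom values), with adjustment over the 35 lists in each comparison. The same test with a correlation estimated per list, and fry, were run beside it. The lists, written before the data were examined, were hematopoietic stem and progenitor markers; erythroid markers; heme synthesis and iron handling, neutrophil primary granule and promyelocyte markers, late neutrophil markers, monocyte markers, resident macrophage markers, B lineage markers, plasma cell markers, T and NK cell markers, megakaryocyte and platelet markers. Further lists were eosinophil, basophil and mast cell markers; dendritic cell markers, MHC class II presentation, mesenchymal stromal and osteoblast markers, adipocyte markers, endothelial markers, osteoclast markers, skeletal muscle markers, S phase genes, G2 and mitosis genes, p53 target genes and DNA repair genes. The remaining lists were apoptosis regulators, interferon-stimulated genes, inflammatory cytokines and NF-kB genes, NRF2 and antioxidant genes, oxazaphosphorine and aldehyde metabolism, oxidative phosphorylation genes, glycolysis and hypoxia genes, cytosolic ribosomal proteins, hematopoietic growth factors and receptors, JAK-STAT pathway genes, PI3K-AKT-mTOR and FoxO genes, and early response genes. Marker lists describe transcripts in bulk RNA, not cell numbers.

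The main test, the named-gene rule, the lists and most alternatives were chosen before the data were examined. For each comparison the text names the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold, with a mean CPM of at least 1 and no overlap between groups, leaving out clone and predicted-gene names. Immunoglobulin and T cell receptor segments were also left out. It also names up to 4 members of each described list with the smallest p, and the 10 genes that moved back with the largest smaller change of the 2 comparisons. Genes named outside this rule are marked as chosen after their values were seen.

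Genes that moved back were those past the threshold in model against control and in cornus against model with opposite signs. Because both comparisons use the model libraries, the count was set beside 20 simulations of unchanged groups, beside independent lists of the same sizes, and beside all 6 divisions of the model libraries into pairs. The grouping of samples was also set against the 35 ways of splitting 8 libraries 4 and 4, with the larger count of the 2 labelings of a split for the genes that moved back.

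Alternatives were DESeq2 size factors, upper-quartile factors, no filter, a filter of CPM 1 in 4 libraries, the DESeq2 1.42.0 Wald test, limma-voom, only the 2 groups compared, replicate number as a block, the 20 most abundant genes left out, a log2 change over 1, unadjusted p, limma on log2 of FPKM with 1 or 0.1 added, and each library left out. Chosen after seeing the data were controls 1 to 3 summed to 1 sample (10 libraries), removal of a trend with gene length and GC, and a fit without model 1 and cornus 1.

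The code was tested on simulated data with 50 genes changed at each of 4 sizes per comparison. At a 2-fold change, 62%, 62% and 64% were recovered in the 3 comparisons, and at 1.5-fold 28%, 24% and 24%, with 4, 3 and 7 false calls. A list shifted 1.5-fold was recovered and 0 other lists were called. The simulated genes varied independently, so this does not show how often lists of genes that vary together are called falsely. The simulated libraries were also drawn as separate samples, with the spread of the main fit. Controls 1 to 3, whose counts were nearly the same, enter that spread, so recovery may be too high and false calls too few.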

Results

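RNA from bone marrow cells of wild-type mice was sequenced after poly(A) selection in 12 samples, 4 in each of 3 groups. The control group had no treatment, the model group had myelosuppression induced by CTX, and the cornus group received nanoparticles that self-assemble from Cornus officinalis, the Asian dogwood. The labels do not say whether the cornus mice were also given CTX. The design text calls the samples biological replicates, but nothing in the labels says whether the 4 samples of a group came from separate animals, so the p-values measure the spread between these samples. The deposited table held read counts for 21958 genes. Controls 1 to 4 summed to 16385077, 17004627, 15470686 and 14746287 counts, model samples 1 to 4 to 15004633, 14194199, 14674952 and 18330180, and cornus samples 1 to 4 to 13919266, 13902122, 15850079 and 19139771.

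Hemoglobin transcripts, the main product of maturing red cells, took 2.49%, 2.47% and 2.45% of the counts in controls 1 to 3 and 9.80% in control 4 (95% exact binomial interval 9.79% to 9.82%). The model libraries had 0.0249% (0.0241% to 0.0257%), 0.942%, 0.463% and 0.332%, and the cornus libraries 0.0218% (0.0211% to 0.0226%), 1.57%, 0.448% and 1.40%. Intervals and floors cover counting error only, since PCR reads without molecular identifiers are not independent molecules. The controls separated from the model and cornus libraries on the first principal component of log2 CPM, which held 54.5% of the variance and on which model and cornus libraries overlapped. Control 4 lay apart from the other controls on it.

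Controls 1 to 3 had nearly the same counts over the abundant genes as a whole. Over genes with at least 20 counts in a pair of libraries, chi-square per degree of freedom was 1.72 to 1.92 between them and 12.9 to 147 in the other 15 pairs within a group. Their biological coefficient of variation was 2.20%, against 19.2% to 26.0% in other sets of 3 libraries of 1 group. Each comparison with the control group is therefore also given with controls 1 to 3 summed to 1 sample, a fit chosen after the data were seen. A gene is said to have risen or fallen against control only where it passed the threshold in both fits, and control values are given as the mean of controls 1 to 3 followed by control 4.

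**Figure D1:**
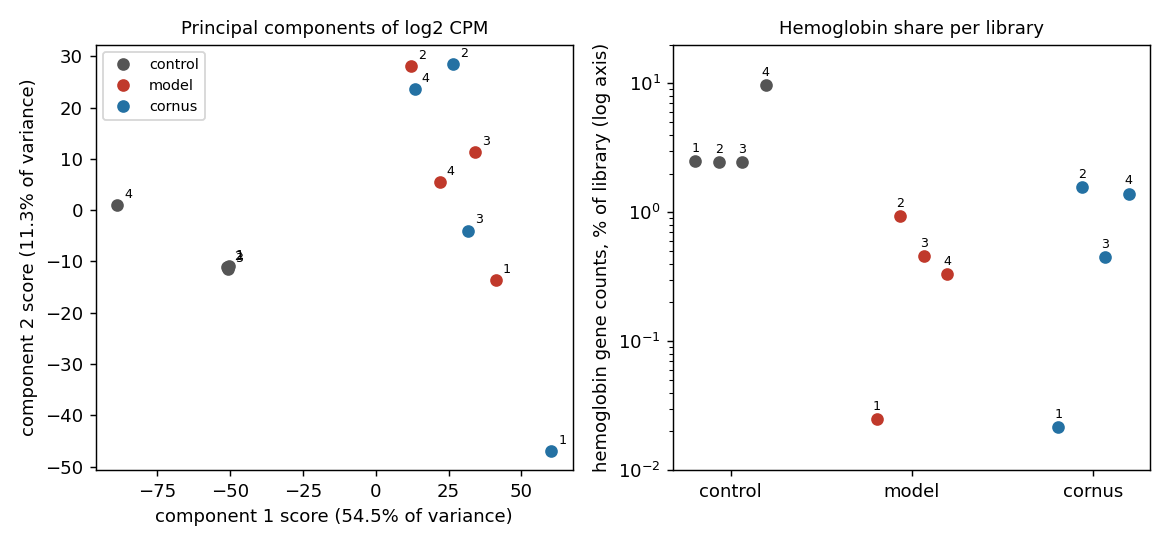
Left, the first principal component (54.5% of the variance) against the second (11.3%) of log2 CPM, with 1 point per library. Right, the percentage of counts from hemoglobin genes in each library on a log axis, where control 4 reaches 9.80% and model 1 and cornus 1 lie at 0.0249% and 0.0218%.

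The comparison of the model group with control asks what CTX did to the marrow's transcripts. Many transcripts of eosinophils and B cells were far lower. Alox15, a lipoxygenase of eosinophils, fell by 7.88 ± 0.32 on the log2 scale (SE), to 1.06 ± 0.667 CPM (SD, n = 4) from 249 and 239 CPM in the controls (edgeR adjusted p = 7.23e-08, 1.30e-05 with controls 1 to 3 summed). Ms4a1, which encodes a B cell surface antigen, had 2 counts in the 4 model libraries together and 5268 in the 4 controls, 2748-fold lower with a counting interval of 760.3 to 22695. Interferon-induced genes moved the other way: Oas1g, an antiviral oligoadenylate synthetase, rose by 3.62 ± 0.17 to 68.4 ± 7.21 CPM (SD, n = 4) from 5.98 and 4.28. In the deposited coordinates, whose genome build no source names, Alox15 (ENSMUSG00000018924) lies on chromosome 11 at 70234978 to 70242857 and Ms4a1 (ENSMUSG00000024673) on chromosome 19 at 11227039 to 11243605.

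Of 12549 genes tested with edgeR, 5531 passed the threshold, 2907 higher and 2624 lower in the model group than in control. The change was over 1 on the log2 scale for 681 of the higher and 853 of the lower genes. With controls 1 to 3 summed, 4339 passed, 2259 higher and 2080 lower, and 2217 and 1987 genes passed in both fits. A test of the deposited FPKM with limma called 3145 genes higher and 1840 lower, a share higher of 63.1% against 52.6% in the count test. The 4 model values and the 4 control values did not overlap in 5532 genes, 44.1% of those tested. Chance gives 2.86% if the 4 controls are separate samples, and a larger share if controls 1 to 3 are 1 sample.

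Iigp1, an interferon-inducible GTPase, had the largest rise against control. It rose by 5.70 ± 1.05 to 277 ± 388 CPM (SD, n = 4) from 5.88 and 3.49, with 99.0, 143, 853 and 10.9 CPM in model samples 1 to 4. The antiviral gene Oas1h rose by 5.43 ± 0.49, the guanylate-binding genes Gbp2b and Gbp10 by 5.43 ± 1.22 and 4.38 ± 0.76, the chemokine Cxcl9 by 4.94 ± 1.10 and the cytotoxic protease Gzmb by 4.88 ± 0.93. Adgrb1, an adhesion receptor, rose by 4.98 ± 1.10, the endothelial lipase Lipg by 4.90 ± 0.96 and the matrix protein Spon1 by 4.48 ± 0.37. Vmn2r97, a vomeronasal receptor, was higher by 5.12 ± 1.43 (edgeR adjusted p = 0.0130), but not past the threshold with controls 1 to 3 summed (0.0773) or without model 3 (0.0571). Model 3 had by far the highest value in several of these genes: 53.6 CPM of Gbp2b against 0.803 to 5.56 in the other model libraries, 133 of Cxcl9 against 2.76 to 15.8, 19.9 of Adgrb1 against 0.853 to 2.22, 142 of Gzmb against 4.57 to 52.7, and 44.7 of Vmn2r97 against 0.755 to 6.24. Reads of the Oas1, Gbp and vomeronasal families can be shared between near-identical copies, so the values of single members are uncertain.

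Fcmr, the IgM receptor of B cells, had 2359 counts in the controls and was at least 820.3-fold lower in the model group, where its count was below the floor of 3 counts over the group. Klhl14 and the IgE receptor gene Fcer2a fell by 7.12 ± 0.72 and 6.78 ± 0.51. The eosinophil ribonucleases Ear1 and Ear2, which are close paralogs, fell, with log2 changes of -7.04 ± 0.46 and -5.63 ± 0.47. The calcium channel gene Cacna1i fell by 6.24 ± 0.59. The fatty acid receptor Ffar1 had 3 counts against 235, 81.7-fold lower (27.6 to 399), and Hba-a2, whose reads can go to its near-identical copy Hba-a1, had 3 against 253, 88.0-fold lower (29.8 to 429).

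Granulocyte genes went in both directions in the model group against control. Of 18 eosinophil, basophil and mast cell markers, 17 were called lower (18 adjusted over the list alone, 15 with controls 1 to 3 summed), with a median log2 change of -3.36 (camera adjusted p = 1.23e-12, or 0.436 with an estimated correlation). The eotaxin receptor Ccr3 fell by 4.42 ± 0.33 to 1.23 ± 0.474 CPM from 25.4 and 30.9. Late neutrophil markers had a median of -0.95, and 15 of 23 were called lower (15 over the list alone, 10 summed; camera adjusted p = 6.87e-06, or 0.632 with an estimated correlation). Clec4d, a lectin receptor of mature neutrophils, fell (-4.46 ± 0.21), as did Retnlg (-3.78 ± 0.50), the formyl peptide receptor Fpr1 (-1.74 ± 0.30) and the G-CSF receptor Csf3r (-1.45 ± 0.18). Primary granule and promyelocyte genes, made earlier in the same lineage, had a median of 0.86, and 8 of 13 were called higher in all 3 ways (camera adjusted p = 0.00245, or 0.632 with an estimated correlation). Ctsg rose by 1.47 ± 0.26, Prtn3 by 1.31 ± 0.24, Cst7 by 1.21 ± 0.20 and Mpo, myeloperoxidase, by 1.03 ± 0.19 to 2849.7 ± 655 CPM from 1436 and 1284. Control 4 itself lay below controls 1 to 3 by a median of -0.60 in the late and -0.34 in the early neutrophil genes.

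B lineage markers were lower in the model group than in control, while camera did not call plasma cell markers. Of 23 B lineage markers, 18 were called lower (19 adjusted over the list alone, 17 with controls 1 to 3 summed), with a median of -3.68 (camera adjusted p = 3.65e-11, or 0.605 with an estimated correlation). The complement receptor Cr2 fell by 3.94 ± 0.40 and the B cell co-receptor Cd22 by 3.71 ± 0.38. Among 9 plasma cell markers, 4 were called lower and 1 higher, or 4 lower alone with controls 1 to 3 summed. Their median was -0.05 and their mean -1.14 (camera adjusted p = 0.172), and Jchain, which joins antibody subunits, fell by 4.76 ± 0.56, Irf4 by 3.08 ± 0.39 and Sdc1 by 2.07 ± 0.29. Control 4 was above the other controls by a median of 0.94 in B lineage and 0.66 in plasma cell markers.

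T and NK cell markers had 8 of 22 called lower and 3 higher in the model group against control (8 and 4 over the list alone, 7 and 2 summed). Their median was -0.84, and the T cell receptor chains Cd3e, Cd3g and Cd3d fell by 4.45 ± 0.35, 2.91 ± 0.41 and 2.37 ± 0.30, while Gzmb rose. The list was called (camera adjusted p = 0.0415, or 0.662 with an estimated correlation). It was not called without control 4 (median -0.57, 0.0512) or model 4 (-0.87, 0.222). Of 10 genes of MHC class II presentation, 6 were called lower and 1 higher in every count, with a median of -1.19 (camera adjusted p = 0.0254, or 0.632 with an estimated correlation). H2-Ob fell by 2.84 ± 0.53, the invariant chain Cd74 by 1.95 ± 0.46 and H2-Oa by 1.23 ± 0.28, whereas H2-DMb1 rose by 0.66 ± 0.13. Dendritic cell markers had 7 of 16 called lower and 2 higher (the same over the list alone, 4 and 1 summed). Among them Cd209d fell by 3.64 ± 0.47 and Ly6d by 2.14 ± 0.40. That list's camera adjusted p was 0.0789, and 0.0312 without cornus 1.

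Red cell genes were lower in the model group than in control, with large differences between libraries. All 24 erythroid markers had lower values, with a median of -1.77, and 5 were called lower (3 adjusted over the list alone, 4 with controls 1 to 3 summed; camera adjusted p = 0.00301, or 0.673 with an estimated correlation). Carbonic anhydrase Car1 fell by 1.67 ± 0.37 and the hemoglobin gene Hbb-bt by 4.24 ± 1.21, to 186 ± 137 CPM from 1762 and 8772. Of 19 genes of heme synthesis and iron handling, 6 were called lower and 1 higher in every count, with a median of -1.16 (camera adjusted p = 0.00301, or 0.632 with an estimated correlation). The heme oxygenase Hmox1 fell by 1.25 ± 0.15 and the ferritin chains Fth1 and Ftl1 by 1.30 ± 0.26 and 1.03 ± 0.20, while Alas1 rose by 0.94 ± 0.21. Control 4 exceeded the other controls by a median of 1.15 in erythroid and 0.90 in heme genes.

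Stem and progenitor markers were mixed in the model group against control, with 3 of 18 called higher and 2 lower (the same over the list alone, 2 and 2 summed) and a median of 0.35 (camera adjusted p = 0.698). The stem cell regulator Hlf rose by 0.76 ± 0.17, whereas Gata2 and Sox4 fell by 1.80 ± 0.29 and 1.03 ± 0.28. Megakaryocyte and platelet markers had a median of 0.68, with 3 of 19 called higher and 1 lower. Over the list alone, and with controls 1 to 3 summed, Nfe2 (fell by 0.51 ± 0.12) was the only member called. The list's camera adjusted p was 0.276, and 0.0276 without cornus 3. Monocyte markers had 4 of 17 called higher and 2 lower (the same over the list alone, 3 and 1 summed; camera adjusted p = 0.355). Spn rose by 0.60 ± 0.09 and Treml4 fell by 1.10 ± 0.27, and control 4 lay below the other controls by a median of -1.07. Resident macrophage markers had a median of -0.61, and 11 of 20 were called lower (11 over the list alone, 9 summed; camera adjusted p = 0.00301, or 0.605 with an estimated correlation). Transferrin Trf fell by 1.30 ± 0.12, the mannose receptor Mrc1 by 1.15 ± 0.20 and Adgre1, which encodes F4/80, by 1.01 ± 0.13.

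Endothelial and skeletal muscle markers were lower in the model group than in control as lists, while camera did not call stromal, adipocyte and osteoclast markers. The fry test called 4 lists that camera did not, among them adipocyte (adjusted p = 0.00371) and osteoclast (0.0218) markers, both lower. Of the lists that camera called in this comparison, fry did not call erythroid (0.145), ribosomal (0.145) and glycolysis (0.0522) genes. Of 16 endothelial markers, 5 were called lower (5 adjusted over the list alone, 4 summed), with a median of -0.73 (camera adjusted p = 0.0239, or 0.632 with an estimated correlation). The scavenger receptor Stab2 fell by 1.66 ± 0.33 and the fatty acid carrier Fabp4 by 1.76 ± 0.32. Of 19 stromal and osteoblast markers, 7 were called lower and 1 higher (the same over the list alone, 5 and 1 summed; camera adjusted p = 0.172). Alkaline phosphatase Alpl fell by 3.22 ± 0.61 and collagen Col1a1 by 2.52 ± 0.58, while Pdgfrb rose by 0.59 ± 0.12. Of 9 adipocyte markers, 4 were called lower and 1 higher (4 and 2 over the list alone, 3 and 1 summed; camera adjusted p = 0.172), and the desaturase Scd1 fell by 3.10 ± 0.27 while Acaca rose by 1.35 ± 0.12. Of 8 osteoclast markers, 4 were called lower and 1 higher (the same over the list alone, 3 and 1 summed; camera adjusted p = 0.172), and acid phosphatase Acp5 fell by 1.67 ± 0.33. All 6 skeletal muscle markers had lower values and 4 were called lower in every count, with a median of -0.95 (camera adjusted p = 0.0150, or 0.605 with an estimated correlation), but without the filter on low counts the list was not called (0.0896). The myosin-binding gene Mybpc2 fell by 3.85 ± 0.56. Control 4 was above the other controls by a median of 0.57 in stromal, 0.64 in adipocyte and 0.41 in muscle genes.

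Interferon-stimulated genes rose as a group in the model samples against control. Of 37 members, 32 were called higher (33 adjusted over the list alone, 29 with controls 1 to 3 summed), with a median of 1.56 (camera adjusted p = 2.87e-11, or 0.605 with an estimated correlation). Ifi44 rose by 4.07 ± 0.37, Oas1a by 1.77 ± 0.16 and Oasl1 by 1.75 ± 0.16. Control 4 lay below the other controls by a median of -0.72 in this list. Of 25 inflammatory cytokine and NF-kB genes, 13 were called lower and 3 higher (the same over the list alone, 6 and 1 summed). The cytokine Il1b fell by 5.14 ± 0.33 to 1.26 ± 0.509 CPM from 41.5 and 54.0, the chemokine Ccl6 by 2.82 ± 0.28 and the interleukin 1 antagonist Il1rn by 2.29 ± 0.42. That list had a median of -0.39 and was called (camera adjusted p = 0.0321, or 0.632 with an estimated correlation), but not without control 1 (0.0651), control 2 (0.0610), control 3 (0.0646) or model 4 (0.180), and not with controls 1 to 3 summed (0.109).

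Camera called no common direction for the lists of signalling genes in the model group against control, apart from early response genes. Of 20 early response genes, 11 were called lower and 1 higher (11 and 2 over the list alone, 9 lower summed), with a median of -0.57 (camera adjusted p = 0.00301, or 0.605 with an estimated correlation). The transcription factor genes Egr3 and Klf2 fell by 2.66 ± 0.42 and 1.89 ± 0.23, and control 4 was above the other controls by a median of 0.53. Of 23 hematopoietic growth factors and receptors, 6 were called higher and 5 lower (6 and 6 over the list alone, 5 and 3 summed). Their median was 0.18 and their mean -0.09 (camera adjusted p = 0.944, upward, where fry gave a downward sign), and Il6st rose by 1.03 ± 0.19 while Tgfbr2 fell by 0.99 ± 0.11. Of 25 JAK-STAT pathway genes, 8 were called higher and 5 lower (the same over the list alone, 6 and 3 summed; camera adjusted p = 0.355). Stat2 rose by 1.49 ± 0.28 and Jak2 by 0.67 ± 0.13. Of 25 genes of PI3K-AKT-mTOR and FoxO signalling, 9 were called higher and 4 lower (the same over the list alone, 8 and 3 summed; camera adjusted p = 0.209), and Foxo1 fell by 1.68 ± 0.25.

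Mitosis and DNA repair genes were higher in the model group than in control. Of 33 genes of G2 and mitosis, 18 were called higher and 3 lower (the same over the list alone, 13 and 3 summed), with a median of 0.27 (camera adjusted p = 0.00301, or 0.662 with an estimated correlation). The kinetochore genes Cenpe and Cenpf rose by 0.85 ± 0.07 and 0.74 ± 0.12. Of 38 DNA repair genes, 17 were called higher and 4 lower (18 and 4 over the list alone, 10 and 4 summed), with a median of 0.29 (camera adjusted p = 0.00983, or 0.632 with an estimated correlation). The damage kinases Atm and Atr rose by 1.75 ± 0.17 and 0.99 ± 0.11 and Rev3l by 0.94 ± 0.09, while the ligase Lig4 fell by 1.54 ± 0.15. The DNA repair list was not called without the trend with gene length and GC described below (0.0534). S phase genes had 4 of 32 called lower and 3 higher (3 and 2 over the list alone, 4 and 1 summed), with a median of -0.01 and camera upward (adjusted p = 0.944). Hells rose by 0.78 ± 0.11 and Pcna fell by 0.47 ± 0.14. Of 27 p53 target genes, 8 were called higher and 6 lower (8 and 7 over the list alone, 3 and 5 summed; camera adjusted p = 0.802). Of 28 apoptosis regulators, 9 were called higher and 5 lower (the same over the list alone, 6 and 5 summed; camera adjusted p = 0.840), among them Apaf1, which rose by 0.84 ± 0.14, and Bmf, which fell by 1.44 ± 0.20.

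Respiratory chain and ribosomal genes were lower in the model group than in control as lists. The share of counts from genes of the mitochondrial genome was higher, at 1.94% to 2.50% in the model libraries against 1.42% to 1.65% in the controls. Of 53 oxidative phosphorylation genes, 33 were called lower and 2 higher (41 and 2 over the list alone, 35 lower summed), with a median of -0.40 (camera adjusted p = 2.00e-07, or 0.632 with an estimated correlation). Without the trend with gene length and GC described below, the median was -0.09 (0.0299). Ndufa1 fell by 1.01 ± 0.17 and Cox6c by 0.69 ± 0.14. Of 73 cytosolic ribosomal protein genes, 65 had lower values and 19 were called lower (14 over the list alone, 19 summed), with a median of -0.25 (camera adjusted p = 0.000742, or 0.689 with an estimated correlation), which turned to 0.05 once the trend with gene length and GC was removed. Rpl30 fell by 1.62 ± 0.26. Control 4 was above the other controls by a median of 0.47 in both lists. Of 28 NRF2 and antioxidant genes, 12 were called lower and 4 higher (the same over the list alone, 10 and 4 summed), with a median of -0.35 (camera adjusted p = 0.0253, or 0.585 with an estimated correlation). The peroxidase Gpx1 fell by 2.49 ± 0.35 and Taldo1 by 1.10 ± 0.11. Of 16 genes that metabolize oxazaphosphorines and aldehydes, 4 were called lower and 3 higher (5 and 5 over the list alone, 2 and 3 summed; camera adjusted p = 0.713), and the efflux pump Abcb1b rose by 1.17 ± 0.24. Of 28 glycolysis and hypoxia genes (27 symbols, 1 of which belongs to 2 genes), 9 were called higher and 3 lower (the same over the list alone, 6 and 1 summed), with a median of 0.30, and Ero1a rose by 1.28 ± 0.19 and Vegfa by 0.95 ± 0.18. The glycolysis list was called (camera adjusted p = 0.0300, or 0.662 with an estimated correlation), but not without control 4 (0.110), model 3 (0.0580) or model 4 (0.0690).

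Longer genes lay higher in the model group than in control. The rank correlation of the log2 change with the deposited gene length was 0.322 across the 12549 genes, which are not independent replicates, and 0.364 in the cornus group against control and 0.109 in cornus against model. Genes called higher in the model group had a median length of 6493 bases and those called lower 3351. After removal of a trend with length and GC, 4384 genes were called, 3569 of them among the 5531, and the DNA repair, inflammatory and ribosomal lists lost their call (camera adjusted p = 0.0534, 0.0540 and 0.972), with medians of 0.23, -0.22 and 0.05, while dendritic cell markers gained one (0.0446). In cornus against control, monocyte markers gained one (0.0345).

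**Figure D2:**
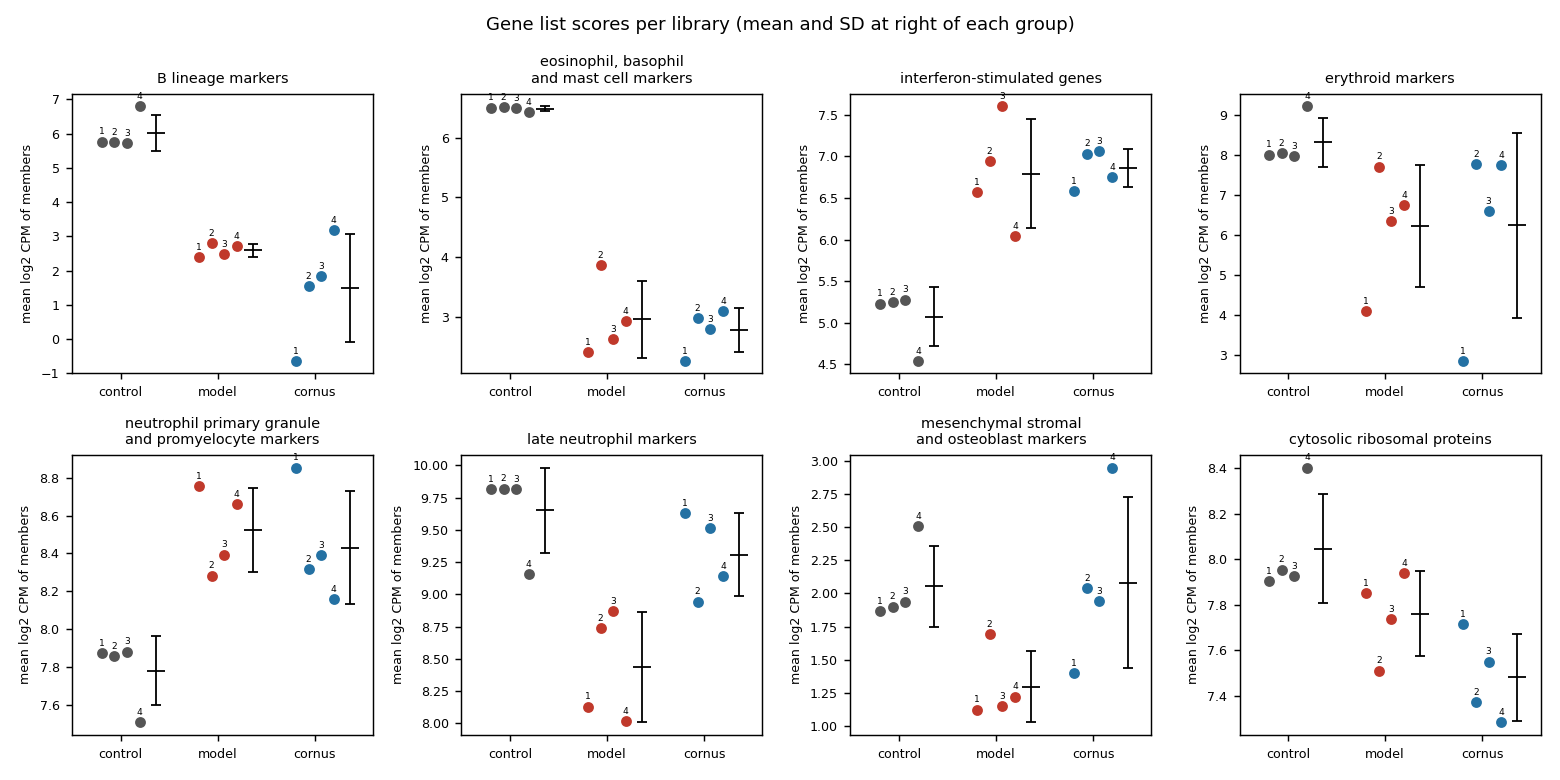
Mean log2 CPM of the members of 8 gene lists in each of the 12 libraries, with points numbered by replicate and the mean ± SD of each group of 4 at the right. B lineage and eosinophil, basophil and mast cell genes lie lower in both the model and the cornus group than in control (median log2 changes of -3.68 and -3.36 in the model group), and interferon-stimulated genes lie higher (1.56).

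The comparison of the cornus group with the model group asks how marrow of mice given the nanoparticles differed from marrow of the CTX model. Few single genes stood out. The scavenger receptor gene Stab1 was higher in cornus by 1.47 ± 0.21 on the log2 scale, at 6.02 ± 1.70 against 2.17 ± 0.192 CPM (SD, n = 4 each; edgeR adjusted p = 0.0232), with 8.24 and 6.06 CPM in the controls. Taf4b, a subunit of a general transcription factor, was lower, at 8.29 ± 1.18 against 16.6 ± 1.12 CPM (SD, n = 4 each; edgeR adjusted p = 0.0232), with 7.06 and 7.84 CPM in the controls.

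In total edgeR called 19 of 12549 genes, 10 higher and 9 lower in cornus than in model, while 2615 genes had an unadjusted p under 0.05. The values of the groups did not overlap in 1694 genes, 13.5% of those tested, where chance gives 2.86% on average. The share in other splits of these libraries was not computed, so this does not exclude chance. The DESeq2 Wald test called 853 genes (451 higher, 402 lower), limma-voom 9 (4 and 5) and limma on FPKM 634, of which 58 were higher and 576 lower, a share higher of 9.15% against 52.6% in the count test. The FPKM values moved the median log2 change of all genes by -0.10. With controls 1 to 3 summed, edgeR called 0 genes, with 2310 at an unadjusted p under 0.05 and a smallest adjusted p of 0.106. The near-identical controls enter the estimate of the spread that all 3 groups share. The count was 0 without control 1, control 2, control 3, model 1, model 3, model 4, cornus 3 or cornus 4 (1976 to 2727 genes at an unadjusted p under 0.05), 1 without cornus 1, 28 without cornus 2, 63 without model 2 and 1035 without control 4. None of the 19 genes was therefore called in every fit that left out 1 library.

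Among the 10 genes called higher in cornus than in model, Ushbp1 was higher by 2.05 ± 0.28, the collagen-processing protease Adamts2 by 1.84 ± 0.30, Adtrp, a regulator of the coagulation inhibitor TFPI, by 1.45 ± 0.23 and Igfbp7 by 1.44 ± 0.24. Dnah8 was higher by 1.25 ± 0.18, Ypel3 by 0.83 ± 0.14, Pbxip1 by 0.77 ± 0.13, the calcium release channel Itpr2 by 0.71 ± 0.10 and Rgl2 by 0.58 ± 0.09. Of the genes called lower, the desaturase Scd1 had a log2 change of -1.81 ± 0.30 and the meiosis gene Mnd1 of -1.15 ± 0.16. Zfp961 had -0.69 ± 0.10 and the purine synthesis gene Ppat -0.53 ± 0.09. Rrn3 and Taf1d, which serve RNA polymerase I, both had -0.49 (SE 0.06 and 0.08), the nucleolar gene Nop14 had -0.59 ± 0.09 and the exosome nuclease Dis3 -0.56 ± 0.09. All 19 genes had no overlap between the 4 cornus and the 4 model values, and their adjusted p lay between 0.0232 and 0.0485, or 0.106 and 0.154 with controls 1 to 3 summed.

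**Figure D3:**
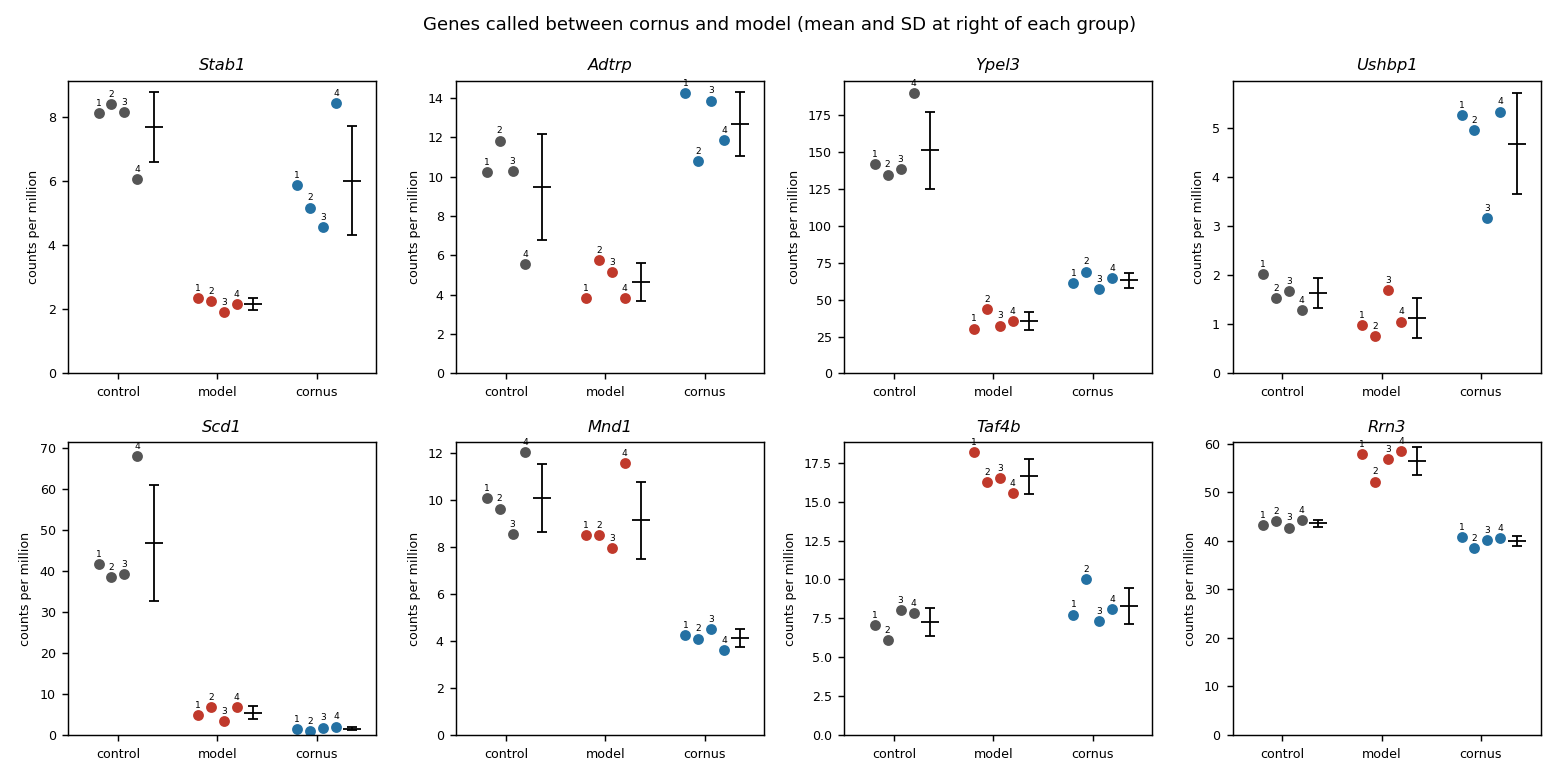
CPM of 8 genes called between cornus and model in each library, with the mean ± SD of each group of 4. Stab1, Adtrp, Ypel3 and Ushbp1 lie higher and Scd1, Mnd1, Taf4b and Rrn3 lower in cornus than in model, with Stab1 at 6.02 against 2.17 and Rrn3 at 40.0 against 56.3 CPM.

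Late neutrophil, macrophage, stromal, endothelial, osteoclast and platelet genes were higher in cornus than in model as lists in camera. The fry test called none of them, with adjusted p of 0.109 for late neutrophil, macrophage and osteoclast, 0.164 for endothelial, 0.253 for stromal and 0.628 for platelet genes, and 28 of 35 splits of the 8 libraries gave as many camera calls. All 23 late neutrophil markers had higher values, with a median of 0.79 (camera adjusted p = 8.18e-13, or 0.708 with an estimated correlation), and 19 passed when adjusted over the list alone (13 with controls 1 to 3 summed). Single members missed the threshold over all genes: the iron-binding protein Lcn2 had 0.84 ± 0.20, at 4629.6 ± 1053 against 2594 ± 496 CPM (SD, n = 4 each; edgeR adjusted p = 0.0737), Retnlg 1.72 ± 0.46 and Padi4 1.07 ± 0.26. Resident macrophage markers had a median of 0.50 (camera adjusted p = 1.18e-05, or 0.557 with an estimated correlation; 5 over the list alone, 3 summed), with Mertk at 0.99 ± 0.26 and Mrc1 at 0.78 ± 0.20. Stromal and osteoblast markers had a median of 1.14 (camera adjusted p = 0.000124, or 0.833 with an estimated correlation; 9 higher and 1 lower over the list alone, 7 and 1 summed), with the matrix gene Sparc at 1.09 ± 0.25. The mean log2 CPM of the stromal list was 1.40 in cornus 1, within the range of the model libraries (1.12 to 1.69), and the macrophage list was 4.03 in cornus 3 and 4.04 in model 3. All 16 endothelial markers had higher values, with a median of 0.61 (camera adjusted p = 2.52e-05, or 0.781 with an estimated correlation; 3 over the list alone and summed), among them Stab2 at 1.45 ± 0.33. The mean log2 CPM of the endothelial list was 1.23 in cornus 3, within the range of the model libraries (1.22 to 1.47), and 2.21 to 2.55 in the other cornus libraries. Osteoclast markers had a median of 0.72 (camera adjusted p = 0.00300, or 0.557 with an estimated correlation; 2 over the list alone and summed). All 19 megakaryocyte and platelet markers had higher values, with a median of 0.56 (camera adjusted p = 0.00300, or 0.908 with an estimated correlation), but the list was not called without cornus 2 (0.25, 0.147). The mean log2 CPM of the platelet list was 3.09 in cornus 3, below every model library (3.80 to 4.99), and 5.13 to 6.07 in the other cornus libraries.

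Ribosomal, respiratory chain, S phase and B lineage genes were lower in cornus than in model as lists in camera, and fry called none of them (adjusted p = 0.483, 0.520, 0.628 and 0.616). Of 73 ribosomal protein genes, 72 had lower values, with a median of -0.28 (camera adjusted p = 9.46e-10, or 0.908 with an estimated correlation), and Rpl3 had -0.43 ± 0.15. Of 53 oxidative phosphorylation genes, 49 had lower values, with a median of -0.16 (camera adjusted p = 2.61e-05, or 0.908 with an estimated correlation). S phase genes had a median of -0.15, with 29 of 32 lower (camera adjusted p = 0.0133, or 0.908 with an estimated correlation), and were not called without model 2 (-0.11, 0.0783), model 4 (-0.08, 0.434) or cornus 1 (-0.12, 0.0915). B lineage markers had a median of -0.93, with 19 of 23 lower (camera adjusted p = 0.00300, or 0.908 with an estimated correlation), and were not called without cornus 1 (-0.41, 0.209). The mean log2 CPM of the B lineage list was 3.19 in cornus 4, above every model library (2.39 to 2.80). That of the ribosomal list was 7.72 in cornus 1 and 7.55 in cornus 3, within the range of the model libraries (7.51 to 7.94). The respiratory list in cornus 1 (5.76, model 5.68 to 5.93) and the S phase list in cornus 2 and 4 (6.51 and 6.49, model 6.42 to 6.78) also lay within it. Cornus 1 had the lowest hemoglobin share of the cornus libraries (0.0218%). Scd1 was the only list member among the 19 called genes.

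Among the lineage lists that camera did not call between cornus and model, erythroid markers had a median of -0.06 and a mean of 0.08 (camera adjusted p = 0.949), but a median of 1.04 (0.000203) without cornus 1. That fit kept model 1, whose mean log2 CPM of erythroid markers was 4.09, against 6.36 to 7.72 in the other model libraries. Cornus 1 had 2.85. Model 1 was also the lowest model library in heme genes, and neither list was tested without both libraries. Stem and progenitor markers had a median of -0.18 (0.0814), and were called without model 4 (-0.26, 0.0205), cornus 1 (-0.25, 0.0492) or cornus 2 (-0.38, 0.00624). Interferon-stimulated genes had a median of 0.14 (0.138), and were called without model 3 (0.34, 0.000139) or cornus 1 (0.20, 0.0134). T and NK cell markers had a median of -0.20 (0.671), and of -0.77 (0.00775) without model 4. Dendritic cell markers had a median of -0.22 (0.170), and were called without cornus 2 (-0.34, 0.0308) or cornus 4 (-0.39, 0.0222). Primary granule genes had a median of -0.08 (0.671), and of -0.27 (0.0330) without cornus 1. Monocyte (0.15), eosinophil, basophil and mast cell (-0.33) and plasma cell (-0.15) medians came with adjusted p of 0.274, 0.713 and 0.671. Mitosis (-0.07) and DNA repair (-0.09) genes were called without model 3, with medians of -0.16 (0.000221) and -0.14 (0.00717). MHC class II genes (-0.59) were called without model 1 (-0.80, 0.00260) or cornus 4 (-0.70, 0.0343), p53 targets (0.06) without model 4 (0.14, 0.0444) or cornus 1 (0.09, 0.0330), and heme genes (0.09) without cornus 1 (0.43, 0.00519). In all, 11 lists gained and 3 lost a call when 1 library was left out.

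Some genes changed in opposite directions in the first 2 comparisons. Of the 15 genes called in both comparisons, 14 changed in opposite directions and 1, Scd1, was lower both times (-3.10 ± 0.27, then -1.81 ± 0.30). Stab1 had -1.82 ± 0.21 in model against control and 1.47 ± 0.21 in cornus against model, Adtrp -1.04 ± 0.23 and 1.45 ± 0.23, and Ypel3 -2.09 ± 0.14 and 0.83 ± 0.14. Taf4b rose by 1.20 ± 0.13 in the model group and lay lower again in cornus, at 8.29 against 16.6 CPM. Pbxip1, Dnah8 and Rgl2 were also lower and then higher, and Dis3, Ppat and Taf1d higher and then lower, all by under 1 on the log2 scale in at least 1 of the comparisons. Dnah8 and Itpr2 missed the threshold in model against control with controls 1 to 3 summed (edgeR adjusted p = 0.0953 and 0.0913), and both went beyond control, at 0.64 and 0.41 in cornus against control (0.0118 and 0.00605). Zfp961, higher and then lower, also went beyond control (-0.28, edgeR adjusted p = 0.0332). Ypel3 went only part of the way and stayed below control (-1.26, edgeR adjusted p = 6.24e-05). Independent lists of these sizes would share 4.18 genes in opposite directions. A mean of 0.1 opposite came from 20 simulations of unchanged groups that share the model libraries. Those simulations changed no gene between groups, so few genes could be called in either comparison. Their count therefore does not show how many opposite changes chance would give here.

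Over all genes the correlation of the log2 changes of model against control with those of cornus against model was -0.226, against -0.385 in simulated unchanged groups. The covariance was -0.0822, against -0.0406 simulated, a difference of -0.0415. When the 4 model libraries were split so that each comparison used its own pair, the correlation ran from -0.20 to 0.05 over 6 versions, and the covariance from -0.0842 to 0.0248. The count of genes that moved back was 215, with 30 in the same direction, when model 2 and model 3 served the first comparison, and 0 in edgeR in the other versions. The count was also 0 with controls 1 to 3 summed and without control 1, control 2, control 3, model 1, model 3, model 4, cornus 1, cornus 3 or cornus 4, and 22 without cornus 2, 50 without model 2 and 458 without control 4. DESeq2 gave 466 and limma-voom 7.

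The comparison of the cornus group with control asks how far the treated marrow stood from untreated marrow. It resembled the model group in its largest changes. Alox15 fell by 7.93 ± 0.33 to 0.983 ± 0.404 CPM (SD, n = 4) from 249 and 239 (edgeR adjusted p = 7.28e-08, 1.50e-05 with controls 1 to 3 summed), and Ms4a1 had 3 counts against 5268, 1708-fold lower (584 to 8286). Oas1g rose by 4.03 ± 0.18 to 91.0 ± 19.8 CPM (SD, n = 4) from 5.98 and 4.28. Of 12549 genes, edgeR called 5972, 3013 higher and 2959 lower, of which 833 and 790 changed by over 1 on the log2 scale. With controls 1 to 3 summed, 4942 were called, 2370 higher and 2572 lower, and 2331 and 2476 passed in both fits. Upper-quartile factors gave 2596 higher and 3447 lower, and limma on FPKM 2350 and 2907. The groups did not overlap in 6100 genes, 48.6% of those tested. Here too chance gives 2.86% only if the 4 controls are separate samples, and a larger share if controls 1 to 3 are 1 sample.

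The largest rises of cornus against control were in Oas1h (5.11 ± 0.49), Lipg (4.65 ± 0.95), Spon1 (4.48 ± 0.37), Cdkl2 (4.22 ± 0.74), the potassium channel Kcna3 (4.22 ± 0.54), Gzmb (4.13 ± 0.92), Oas1g and Ifi44 (3.99 ± 0.37). Vmn2r97 was higher by 4.11 ± 1.43 (edgeR adjusted p = 0.0331), but not past the threshold with controls 1 to 3 summed (0.128), nor without control 1 (0.0622), control 2 (0.0765), control 3 (0.0689), control 4 (0.0662), cornus 1 (0.0780) or cornus 3 (0.0688). Among the falls, Fcmr had 3 counts against 2359, 765-fold lower (261 to 3712), Cacna1i 2 against 324, 158-fold lower (43.3 to 1307), and Egfl6 3 against 211, 68.4-fold lower (23.1 to 334). Falls were also found in Ear1 (-7.56 ± 0.48), Fcer2a (-6.99 ± 0.53), Klhl14 (-6.78 ± 0.70), the kinase Srpk3 (-6.01 ± 0.60) and the lipoxygenase Alox12e (-5.76 ± 0.73).

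B lineage and eosinophil genes were lower in cornus than in control, and so were red cell genes, by far the most in cornus 1. All 23 B lineage markers were called lower (23 adjusted over the list alone, 21 with controls 1 to 3 summed), with a median of -4.28 (camera adjusted p = 3.83e-12, or 0.612 with an estimated correlation), and Cd79b fell by 4.50 ± 0.43. Of 18 eosinophil, basophil and mast cell markers, 16 were called lower in every count, with a median of -3.64 (camera adjusted p = 3.51e-12, or 0.526 with an estimated correlation), and the basophil protease Mcpt8 fell by 3.30 ± 0.26. MHC class II genes had 6 of 10 called lower in every count, with a median of -1.79 (camera adjusted p = 0.00901, or 0.612 with an estimated correlation). Dendritic cell markers had 10 of 16 called lower and 1 higher (the same over the list alone, 7 lower summed), with a median of -1.19 (camera adjusted p = 0.0121, or 0.726 with an estimated correlation). T and NK cell markers had 11 of 22 called lower and 2 higher (12 and 3 over the list alone, 9 and 1 summed), with a median of -0.98 (camera adjusted p = 0.0234, or 0.726 with an estimated correlation), but -0.80 and 0.0529 without cornus 1. Erythroid markers had a median of -1.91 and 2 of 24 called lower in every count (camera adjusted p = 0.00589, or 0.743 with an estimated correlation), but -0.84 and 0.0529 without cornus 1. Their mean log2 CPM was 2.85, 7.77, 6.59 and 7.75 in cornus 1 to 4, against 7.98 to 8.06 in controls 1 to 3 and 9.23 in control 4. Heme genes had a median of -1.09, with 5 of 19 called lower and 1 higher (camera adjusted p = 0.0121, or 0.726 with an estimated correlation), but -0.78 and 0.0524 without cornus 1. Control 4 was above the other controls by a median of 1.15 in erythroid and 0.94 in B lineage genes.

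Platelet, interferon and early granule genes were higher in cornus than in control. Of 19 megakaryocyte and platelet markers, 15 were called higher (18 adjusted over the list alone, 5 with controls 1 to 3 summed), with a median of 1.18 (camera adjusted p = 0.0115, or 0.743 with an estimated correlation). The mean log2 CPM of the list was 3.09 in cornus 3, below every control (3.32 to 3.73), and 5.13 to 6.07 in the other cornus libraries. Tubb1 rose by 2.82 ± 0.60, the platelet chemokine Ppbp by 2.51 ± 0.58 and the platelet receptor Gp1ba by 2.43 ± 0.52. Of 37 interferon-stimulated genes, 30 were called higher (32 over the list alone, 28 summed), with a median of 1.77 (camera adjusted p = 1.50e-12, or 0.612 with an estimated correlation). Of 13 primary granule genes, 11 were called higher (11 over the list alone, 8 summed), with a median of 0.74 (camera adjusted p = 0.00441, or 0.726 with an estimated correlation), and Fcnb rose by 0.94 ± 0.19. Glycolysis and hypoxia genes had a median of 0.30 (camera adjusted p = 0.0115, or 0.726 with an estimated correlation). Mitosis genes had a median of 0.21 (camera adjusted p = 0.0234, or 0.743 with an estimated correlation), but 0.0557 without control 3, 0.193 with controls 1 to 3 summed and 0.0810 without the trend with length and GC.

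Late neutrophil markers had a median of -0.29 in cornus against control (camera adjusted p = 0.378), with 3 of 23 called lower and 1 higher. Clec4d fell by 3.91 ± 0.20, Retnlg by 2.05 ± 0.46 and Csf3r by 0.82 ± 0.17. Of 73 ribosomal protein genes, 58 were called lower (61 lower and 1 higher adjusted over the list alone, 53 lower summed), with a median of -0.55 (camera adjusted p = 2.69e-11, or 0.726 with an estimated correlation). Of 53 oxidative phosphorylation genes, 47 were called lower (50 over the list alone, 45 summed), with a median of -0.55 (camera adjusted p = 3.51e-12, or 0.612 with an estimated correlation). Without the trend with length and GC, the ribosomal and respiratory medians were -0.22 and -0.27. Early response genes had 12 of 20 called lower in every count, with a median of -0.70 (camera adjusted p = 0.00589, or 0.612 with an estimated correlation). Skeletal muscle markers had a median of -0.85 (camera adjusted p = 0.0374, or 0.612 with an estimated correlation). The muscle list was not called without cornus 1 (median -0.88, 0.0524) or cornus 2 (-0.81, 0.0607). Nor was it called without the trend with length and GC (-0.47, 0.168) or the filter on low counts (-0.46, 0.0862). Inflammatory genes (0.0540) were called without control 4 (0.0271), model 2 (0.0432), model 3 (0.0458) or cornus 3 (0.0457), and DNA repair genes (0.0745) without control 4 (0.0345). Stem and progenitor, monocyte, macrophage, plasma cell, stromal, endothelial and osteoclast lists had camera adjusted p of 0.638, 0.107, 0.378, 0.140, 0.648, 0.967 and 0.794. With controls 1 to 3 summed, monocyte markers were called higher (median 0.60, 0.0237) and S phase genes lower (-0.33, 0.0261, against -0.19 and 0.211 with 4 controls). Of the lists that camera called in this comparison, fry did not call erythroid (0.141), heme (0.0629), platelet (0.141) and mitosis (0.0572) genes. It called 7 lists that camera did not.

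Against the same controls, model and cornus changed largely the same genes. Of the genes called in both comparisons, 4140 went in the same direction (2248 higher, 1892 lower) and 4 in opposite directions. Independent lists of these sizes would share 1317 in the same and 1315 in opposite directions. Simulated unchanged groups against these controls gave a mean of 2.75 in the same direction. With no gene changed few could be called there, so that count sets no expectation for this overlap. The correlation of the log2 changes across genes was 0.888, against 0.700 simulated, and the covariance 0.684, against 0.0956 simulated, a difference of 0.588. The simulated comparisons also shared their controls, with controls 1 to 3 varying as 1 sample, so the difference leaves out that part at the simulated spread. The controls could not be split into independent pairs because 3 of them are nearly identical. Part of the excess may therefore still come from the shared controls if they vary more than was simulated.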

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

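The tests of a single granulocyte shift, of a trend with length and GC behind the called genes, and of single libraries behind the cornus lists were chosen only after the results were seen. In a group of 4, a library is named here when its gap to the nearest other library divided by the group's range exceeds Dixon's 95% critical value, which chance gives in about 1 in 20 groups. Over all tested genes this happened in 26.2% in the control group, 5.04% in the model group and 4.70% in the cornus group. The chance rate does not hold for the control group, because its libraries other than control 4 are nearly identical.

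Control 4 lay far from the other controls in its TMM factor (gap 0.916 of the range), hemoglobin share (0.995), mitochondrial share (0.859; 1.42% against 1.62% to 1.65%) and share of the 20 most abundant genes (0.936). It was also the library apart in 22 of 35 list scores, high in erythroid, B lineage, S phase and ribosomal genes and low in neutrophil, monocyte and interferon-stimulated genes. Among 47 named genes it was apart in 7: Fcmr, Cacna1i, Ypel3, Scd1, Taf1d and Srpk3 (high) and Stab1 (low). These ratios and counts cannot show whether control 4 is unusual. The other controls are nearly identical, so any separate library would tend to stand apart from them.

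In the model group, 2 list scores had a library apart, dendritic cell and osteoclast markers, both with model 2 high. So did 6 named genes: Alox15, Dnah8 and Itpr2 (model 2 high), Ms4a1 and Kcna3 (model 1 high) and Oas1g (model 3 high). In the cornus group 8 named genes had a library apart, among them Alox15 (cornus 1 low) and Ushbp1 (cornus 3 low). For Fcmr, Ms4a1, Klhl14, Cacna1i and Egfl6 only cornus 4 had any counts, 2 to 5 in all, and for Ms4a1 in the model group only model 1 had any, so the rule says nothing about these libraries there.

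Controls 1 to 3 may come from 1 RNA or 1 pool of RNA. Over the 200 genes most variable in the model and cornus groups, the highest median chi-square of a pair of controls 1 to 3 was 0.883. That is more than counting error alone gives, but far below the at least 129 in pairs with control 4 and at least 28.3 in model or cornus pairs. A lower share of granulocyte RNA in control 4 does not explain its distance, since its lineage list medians spanned 2.22 on the log2 scale, with monocyte markers at -1.07 and erythroid markers at 1.15, where such a shift would move all other lineages by about the same amount.

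Longer genes lay higher in both treated groups than in control, and a length bias of single libraries cannot be told apart from biology. The highest rank correlation with length between 2 libraries of the model or cornus group was 0.114, but pairs of control 4 with the other controls reached 0.260 against 0.322 between the groups. The bound first written used the model and cornus pairs alone, which was wrong because it left out the group that all these comparisons share, and it was changed after the value was seen. Without 341 ribosomal, respiratory chain and erythroid genes the correlation was 0.311, so the trend was not confined to these genes. With so few of 12549 genes left out the correlation could hardly have changed, so this test had little power to decide. The trend does not account for every called gene, since 64.5% remained past the threshold without it.

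The lists that differed between cornus and model could depend on 1 library, since 7 of 10 kept call and direction without each of the 8 libraries. A trend with length and GC does not account for them, as 10 of 10 kept call and direction without it.

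With the 4 controls counted as separate samples, a random assignment of the 8 libraries to groups can be excluded for the gene counts. The real split was the only 1 of 35 with so many genes in model against control (5531, highest other 0), in cornus against control (5972, highest other 0) and in cornus against model (19, highest other 6). The count of genes that moved back was also largest in the real split (14, 1 of 35, highest other 6), with each split given the larger count of its 2 labelings. That correction was made after the values were seen, because the first count had the labels of model and cornus exchanged. Only called genes can move back, so this count repeats the gene counts and cannot exclude chance for the reversal itself. In the other splits that called genes, all of them moved back (6 of 6 and 1 of 1), against 14 of 19 in the real one. For the numbers of lists a random assignment cannot be excluded. In model against control, 2 of 35 splits had as many as the 20 lists called (highest other 20). In cornus against control 8 had as many as the 16 (highest other 17), and in cornus against model 28 as many as the 10 (highest other 22). Why other splits called more lists than the real one was not tested. These exclusions rest on counting near-identical controls as separate samples: with controls 1 to 3 as 1 sample only 15 splits of the control comparisons exist, too few for a share under 0.05, and cornus against model called 0 genes in edgeR (2310 at unadjusted p under 0.05).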

How the results depend on the processing

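The fits with controls 1 to 3 summed, without the length and GC trend, and without both model 1 and cornus 1 are tests chosen only after the results were seen. With upper-quartile factors more genes were lower than higher in model against control (2595 higher, 2942 lower) and in cornus against control (2596 and 3447), and without the length and GC trend the ribosomal median in model against control turned from -0.25 to 0.05 (camera adjusted p = 0.972). Where no reason is given, the cause was not tested.

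Model against control called 5531 genes, 1534 with a log2 change over 1 (1711 when p was also left unadjusted), and 4550 to 5674 when 1 library was left out. Cornus against control called 5972, with 1623, 1753 and 5127 to 6041. All other settings stayed within 1.5 times. The DESeq2 Wald test kept 5503 and 5930 of the called genes, limma-voom 5318 and 5724.

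Cornus against model called 19 genes: 12 without a filter, 853 with DESeq2, 9 with limma-voom, 634 and 632 with FPKM plus 1 or 0.1, 6 without the length and GC trend, 1 without model 1 and cornus 1, 9 with a log2 change over 1, 285 with both that change and p left unadjusted, and 0 with only these 2 groups (2730 genes at unadjusted p under 0.05) or controls 1 to 3 summed (2310). Leaving out 1 library gave 0 to 1035. The 14 genes that moved back became 9, 466, 7, 325, 314, 4, 0, 3, 117, 0 and 0 in the same order, and 0 to 458.

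The correlations do not settle whether replicate numbers pair the samples. Cornus and model libraries of the same number correlated at 0.450, 0.342, -0.0569 and 0.0463. Only numbers 1 and 2 correlated best with their own, where the highest value with another number was 0.0457 and 0.0419. Model and control libraries correlated at 0.14, -0.11, 0.13 and 0.23 (numbers 3 and 4 best with their own), cornus and control libraries at 0.19, -0.14, 0.05 and 0.29 (number 4). With the number as a block, cornus against model called 0 genes (2778 at unadjusted p under 0.05), and 0 moved back.

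Camera called 20, 10 and 16 lists in model against control, cornus against model and cornus against control. With an estimated correlation it called 0, 0 and 0, and fry called 21, 0 and 19. Leaving out 1 library gave 17 to 21, 9 to 14 and 12 to 18.

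Of the named genes, limma-voom no longer called Cxcl9, Gbp2b, Gzmb and Vmn2r97 in model against control, nor Gzmb, Lipg and Vmn2r97 in cornus against control. The FPKM alternative without a filter was not run, since it was meant for a table without counts. In simulated data at these depths, 24% of genes changed 1.5-fold were recovered in cornus against model, so smaller changes would mostly be missed. The simulated libraries were all separate, with a spread estimated with the near-identical controls included, so recovery in the real data may be lower still.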
